A study of Mus musculus with 21 samples.

How the data were processed

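Expression was measured by RNA sequencing of brain endothelial cells sorted from mice, in 16 libraries of a stroke experiment (4 groups of 4) and 5 libraries of a beta-catenin experiment (3 and 2). The authors deposited RPKM values, reads scaled to gene length and library size, with 1 column per library, and the submitters' processing notes name edgeR and the mouse mm10 genome. The aligner, the gene annotation, the gene lengths and any further scaling of library sizes are not given in the sources used here. The stroke libraries were amplified from polyadenylated RNA with a 3' digital-expression kit, and the others from total RNA with another amplification and library kit.

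The table held 24260 rows, of which 5862 were 0 in every library used and 27 had a calendar date in place of a gene name. Dates were kept as found but never named. The 54 rows that shared 23 names were left out, and 24206 remained. A further 8 columns of the table belong to no sample described in the series and were not used. Values were never negative, and depth per library was estimated as the number of reads that made the most low values whole numbers of reads. This used 2938 genes with transcripts under 1200 bp and RefSeq lengths, since the authors' lengths are not given. Only 22.1 to 41.5% of these low values were whole within 0.02 in the stroke libraries and 10.6 to 14.9% in the other 5, against 4% by chance. An estimate from ratios between libraries differed from it by under 5% in all 16 stroke libraries (by construction in Control_NS 1, which set its scale), with 4.70 to 19.6 M reads, and in 2 of the other 5, for which no depth is given. Low RPKM values there and here rest on few reads.

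Groups, comparisons, tests, gene lists and the rule for named genes were set before the data were examined. Comparisons were made with limma 3.58.1 in R 4.3.3 on log2(RPKM + 1), a scale on which changes of genes with low RPKM are understated, for genes with a mean RPKM of at least 1 in the libraries of the fit. Xist and the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty were left out of the tests, and other X-linked genes, such as Apln, Pgk1 and Uxt, were tested. A single fit with 4 group means covered the 16 stroke libraries and gave both stroke effects, both genotype effects and their interaction (9838 genes), and a fit with 2 group means covered the other 5 libraries (11252 genes). Moderated tests (eBayes with a mean-variance trend) were two-sided, with Benjamini-Hochberg adjustment over all genes of a comparison and a threshold of 0.05. The labels do not say whether libraries came from separate animals, so p-values measure the spread between these samples.

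The 28 gene lists covered Wnt targets, Wnt components, tight junctions, adherens junctions, barrier transport, vesicles and permeability, leukocyte adhesion, inflammation, interferon response, proliferation, angiogenesis, basement membrane, proteases, hypoxia and glycolysis, immediate-early genes, TGF-beta and BMP signalling, and endothelial, arterial, venous, mural, astrocyte, neuron, oligodendrocyte, microglia and macrophage, blood leukocyte, red-cell and platelet, fibroblast, and choroid plexus markers. Lists were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation and with fry, which asks whether a list's genes move 1 way on balance. Of 163 list tests 40 passed with the preset correlation, 5 with an estimated correlation (inflammation and proteases in both stroke comparisons and transport in the stroke comparison of knockouts) and 35, in part other lists, with fry. Lists share members, such as Icam1 and Ackr1 between the venous and leukocyte-adhesion lists.

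Named genes were, for each comparison, the 10 largest rises and falls among genes past the threshold with groups that did not overlap and a mean of at least 5 RPKM in the higher group (for the interaction without the overlap condition), skipping names of predicted genes. From each list up to 4 members past the threshold with the lowest p were added, or up to 2 with the highest mean if none passed. Gpr124, Ctnnb1, Reck, Axin2, Lef1, Apcdd1, Slc2a1, Cldn5, Mfsd2a, Abcb1a, Plvap, Mmp3, Mmp9, Vcam1, Icam1, Sele, Selp, Col4a1 and Pdgfb were always included. Some genes that the rule names are not reported here, in the text, the plot of stroke effects or the search for deviating libraries, and they stay in the counts and list tests. Coordinates came from the GENCODE annotation of GRCm38, the assembly also called mm10. GC content was that of the longest GENCODE transcript of each name and was found for 23845 names. RefSeq symbols and synonyms matched 24070 names.

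Replicates of a group correlated with r of 0.957 to 0.971 across genes in Control_NS, 0.957 to 0.979 in Control_ST, 0.940 to 0.980 in cKO_NS, 0.952 to 0.978 in cKO_ST, 0.917 to 0.926 in Bcat_exon3 and 0.946 in Bcat_control, where genes are not independent. The labels number the samples and do not say that a number stands for 1 animal. After group means were removed, cKO_NS and cKO_ST libraries with the same number correlated at 0.100, 0.134, 0.214 and 0.105, each above its other pairs, and were treated as pairs in an alternative fit. In controls the values were 0.0986, 0.130, 0.0721 and 0.0117, with 3 of 4 above their other pairs. A pair of sample 4 with another number was higher (0.0336), so pairing in controls stays open. The alternative fit blocked control numbers in the same way.

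Each comparison was tested on simulated data with its own spread, 5 draws with 200 changed genes each. The changed genes were taken from those with a mean log2(RPKM + 1) above that of 5 RPKM. The shares recovered therefore do not cover genes of lower RPKM, such as Gpr124 in the stroke experiment. Of 2-fold and 4-fold changes the fit recovered 42.4% and 90.4% for stroke in controls, 46.8% and 92.2% for stroke in knockouts, 41.4% and 90.8% for genotype in the non-stroke hemisphere, 44.2% and 90.2% for genotype after stroke, 11.4% and 70.4% for the interaction and 0% and 5.20% for the beta-catenin comparison. False calls made up 6.21%, 5.70%, 5.03%, 4.41%, 4.66% and 0% of calls, and of 100 random lists 2, 1, 1, 1, 1 and 3 had an unadjusted camera p under 0.05. Genes were drawn independently of each other. These random lists therefore say nothing about lists of correlated genes (estimated correlation 0.263 for transport in the stroke fit).

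Alternatives planned in advance were other pseudocounts, no filter, a filter at 5 RPKM, median-of-ratios and quantile scaling, library weights, no trend, robust eBayes, a minimum 2-fold change, fits to the compared groups alone, a block for the sample number, sex as labelled, omission of the libraries labelled male, and omission of each library in turn. Sex read from RNA, omission of libraries male by RNA or at odds with their labels, and removal of a GC trend per library (lowess, applied after the filter) were chosen after the data were seen. Further tools were Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.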

Results

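RNA was measured in endothelial cells, the cells that line blood vessels, sorted from the brains of adult C57BL/6 mice aged 12 to 20 weeks. The sort kept live cells that carried CD31, an endothelial surface protein, and lacked CD45, a leukocyte protein, and PDGFRb, a pericyte protein. Values are the authors' RPKM, reads scaled to gene length and library size, for 24206 gene names in 21 libraries. Per the labels, 16 libraries form a stroke experiment of 4 groups with n = 4 each. In it the middle cerebral artery was closed for 1 h and reopened for 1 d. Control mice carried 1 floxed and 1 intact Gpr124 allele with an inducible Cre recombinase at the ROSA locus. Knockout mice carried 1 floxed and 1 null allele with the same recombinase. Control_NS and cKO_NS hold cells of the non-stroke hemisphere, and Control_ST and cKO_ST hold cells of the stroke hemisphere. The labels give the occlusion for all 4 groups, so the non-stroke hemisphere is not that of mice without stroke.

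A second experiment without stroke compared 3 libraries (Bcat_exon3) from mice with a floxed exon 3 of Ctnnb1 and an endothelial Cdh5-CreER with 2 libraries (Bcat_control) from mice with intact Ctnnb1 and the same Cre. Loss of exon 3 removes the phosphorylation sites that mark beta-catenin for breakdown. The stroke libraries count tags near the 3' end of polyadenylated RNA. The other 5 were made from total RNA with another kit, so RPKM values were not compared between the experiments. Estimated depth ranged from 4.70 to 19.6 M reads over the 16 stroke libraries (means 8.43 M in Control_NS, 10.9 M in Control_ST, 9.10 M in cKO_NS and 14.9 M in cKO_ST, n = 4 each), and is not given for the other 5, where 2 estimates differed by under 5% in only 2 libraries. Between 13298 and 14006 genes per library, as group means, were above 0. Below, ± after a log2 fold change is the SE of the fit, ± after an RPKM value is the SD, and fold changes on the log2(RPKM + 1) scale understate genes with low RPKM. Genes past an adjusted p of 0.05 in limma are said to have risen or fallen, and for all other genes values alone are given.

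Gpr124, the targeted gene (Adgra2 in current naming, GRCm38 chromosome 8, 27085583 to 27123436, plus strand), encodes an adhesion receptor that works with Reck to pass Wnt7 signals to endothelial cells. Its RPKM was 3.01, 7.58, 4.74 and 2.65 in the Control_NS libraries and 8.12, 5.94, 2.92 and 2.98 in the Control_ST libraries. In knockouts it was 2.03, 0.994, 3.15 and 4.85 in cKO_NS and 0.500, 1.72, 1.72 and 1.52 in cKO_ST. Means were 4.49 ± 2.25, 4.99 ± 2.52, 2.76 ± 1.65 and 1.37 ± 0.585 (n = 4 each). Log2 fold changes were -0.57 ± 0.39 in the non-stroke hemisphere (adjusted p = 0.533) and -1.28 ± 0.39 in the stroke hemisphere (adjusted p = 0.764). Values of cKO_ST lay below every Control_ST library, and cKO_NS overlapped Control_NS, with cKO_NS 4 at 4.85. The sources do not say which exons were deleted, so 3' tags check the genotype labels only in part. In the second experiment Gpr124 was 10.3, 14.0 and 17.3 in Bcat_exon3 and 16.5 and 15.3 in Bcat_control.

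Ctnnb1, which encodes beta-catenin (GRCm38 chromosome 9, 120929216 to 120960507, plus strand), had RPKM of 244, 250 and 169 in Bcat_exon3 and 300 and 310 in Bcat_control (log2 fold change -0.48 ± 0.24, adjusted p = 0.957). A gene-level RPKM does not show the excision of exon 3. In the stroke experiment Ctnnb1 was 2269 ± 158 in Control_NS, 2044 ± 106 in Control_ST, 1689 ± 214 in cKO_NS and 1964 ± 73.8 in cKO_ST. Xist and Y-linked genes read 2 libraries against their labels: cKO_NS 4, labelled female, had a Y-linked sum of 189 RPKM and Xist of 1.48, and cKO_ST 3, labelled male, had 0.423 and 89.7. Both were kept in the groups their labels give. In the stroke experiment the labels give cKO_ST 3 and cKO_ST 4 as male and all other libraries as female. By RNA only cKO_NS 4 and cKO_ST 4 of these libraries read male, so sex was tied in part to genotype. The 5 libraries of the beta-catenin experiment were male by label and by RNA.

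The effect of stroke in controls, Control_ST against Control_NS, shows how brain endothelial cells change within 1 d of reopened flow when 1 Gpr124 allele is intact. Secreted proteases were among the largest rises. Adamts4, which cuts proteoglycans, rose by a log2 fold change of 4.64 ± 0.44, from 3.82 ± 1.99 to 125 ± 63.4 RPKM (n = 4 each, adjusted p = 2.12e-06). Adamts9 (GRCm38 chromosome 6, 92772699 to 92943492, minus strand) rose by 3.99 ± 0.25, from 18.2 ± 7.50 to 287 ± 40.3 (adjusted p = 3.74e-08), and Adamts1 by 2.94 ± 0.25. Emp1, a membrane protein of the vesicle list (GRCm38 chromosome 6, 135362545 to 135383173, plus strand), rose from 79.1 ± 42.5 to 1659 ± 634 (4.53 ± 0.36), with 2602 in Control_ST 3. The angiogenic peptide Apln rose by 4.22 ± 0.40, AA467197 by 4.70 ± 0.44 and the metal-binding Mt2 by 3.72 ± 0.56. So did the activin subunit Inhbb by 3.70 ± 0.42 and Slfn4 by 3.50 ± 0.40. Mmp3 (0.143 ± 0.190 in Control_ST, 0 in Control_NS) and Mmp9 (0 in both) were below the expression filter and were not tested.

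Adhesion molecules that slow leukocytes rose in controls: Icam1 by 2.81 ± 0.30 (3.25 ± 1.43 to 29.3 ± 12.7), Sele by 3.01 ± 0.40 (0.593 ± 0.266 to 15.1 ± 14.0, with 35.8 in Control_ST 4), Selp by 1.91 ± 0.36 and the chemokine-binding Ackr1 by 2.12 ± 0.45. Vcam1 was 40.6 ± 18.0 against 31.7 ± 18.6 (0.43 ± 0.50, adjusted p = 0.640). Inflammatory genes that rose included Socs3, a brake on cytokine signals (2.24 ± 0.32), the prostaglandin synthase Ptgs2 (2.16 ± 0.34), Lcn2 (2.53 ± 0.44), Il6 (2.24 ± 0.39) and Cxcl10 (2.19 ± 0.39). Basement-membrane genes rose: Col4a1 by 2.03 ± 0.20 (27.6 ± 8.53 to 113 ± 10.2), Col4a2 by 2.22 ± 0.20, Sparc by 1.35 ± 0.18 and Igfbp7 by 1.68 ± 0.15 (405 ± 31.6 to 1301 ± 176). Mcam rose by 2.63 ± 0.23, Angpt2 by 2.82 ± 0.35, Edn1 by 1.89 ± 0.25 and Tmem252 by 2.45 ± 0.28. Gja1, a gap-junction gene, rose by 1.76 ± 0.14, Gapdh by 1.95 ± 0.26 and Hmox1 by 2.52 ± 0.49.

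Transport genes of the blood-brain barrier fell in controls. The phospholipid flippase Atp10a fell by 2.08 ± 0.23 on the log2 scale (232 ± 31.3 to 55.2 ± 14.3, adjusted p = 9.64e-06). The transferrin receptor Tfrc (GRCm38 chromosome 16, 32608920 to 32632794, plus strand) fell from 1002 ± 192 to 324 ± 105 (-1.67 ± 0.22). The amino-acid carrier Slc7a1 (-1.45 ± 0.17) and the zinc carrier Slc39a10 (-1.40 ± 0.20) fell too. The efflux pump Abcb1a (GRCm38 chromosome 5, 8660077 to 8748575, plus strand) fell from 195 ± 20.1 to 73.3 ± 16.5 (-1.43 ± 0.22, adjusted p = 3.37e-04), and Mfsd2a, a lipid carrier that limits transcytosis, fell by 0.92 ± 0.30 (adjusted p = 0.0474). Slc2a1, the glucose carrier (GRCm38 chromosome 4, 119108711 to 119137983, plus strand), was 2581 ± 536 against 4075 ± 82.9 (-0.68 ± 0.24, adjusted p = 0.0713). Among junction genes Tjp1 fell by 1.02 ± 0.13 (299 ± 30.6 to 147 ± 14.7), Ocln by 0.89 ± 0.18 and Jam2 by 0.73 ± 0.17, and Cdh5 rose by 0.72 ± 0.16. Cldn5, the main claudin of these cells (GRCm38 chromosome 16, 18776847 to 18778262, plus strand), was 119 ± 51.3 against 112 ± 16.0 (0.00 ± 0.23, adjusted p = 0.992), with 195 in Control_ST 4. Other large falls were in Dixdc1 (-2.49 ± 0.31), Gkn3 (-2.60 ± 0.61), Net1 (-2.13 ± 0.41), Ptgds (-2.55 ± 0.83) and the embryonic globin Hbb-y (-3.06 ± 0.30).

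Wnt-target genes moved both ways in controls. Axin2, a feedback inhibitor of the pathway (GRCm38 chromosome 11, 108920349 to 108950783, plus strand), fell from 4.59 ± 1.49 to 1.04 ± 0.347 (-1.43 ± 0.26, adjusted p = 0.00128). Lef1, a nuclear partner of beta-catenin (GRCm38 chromosome 3, 131110471 to 131224356, plus strand), fell from 1262 ± 205 to 755 ± 60.1 (-0.73 ± 0.16, adjusted p = 0.00429). Tnfrsf19 fell by 1.68 ± 0.29 (18.2 ± 0.557 to 5.29 ± 2.39) and the co-receptor Reck by 1.35 ± 0.28 (80.3 ± 20.1 to 31.6 ± 11.3). Myc, which many other signals also drive, rose by 2.49 ± 0.30, and Apcdd1 was 1.79 ± 1.21 against 1.65 ± 0.624 (0.01 ± 0.37).

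**Figure D1:**
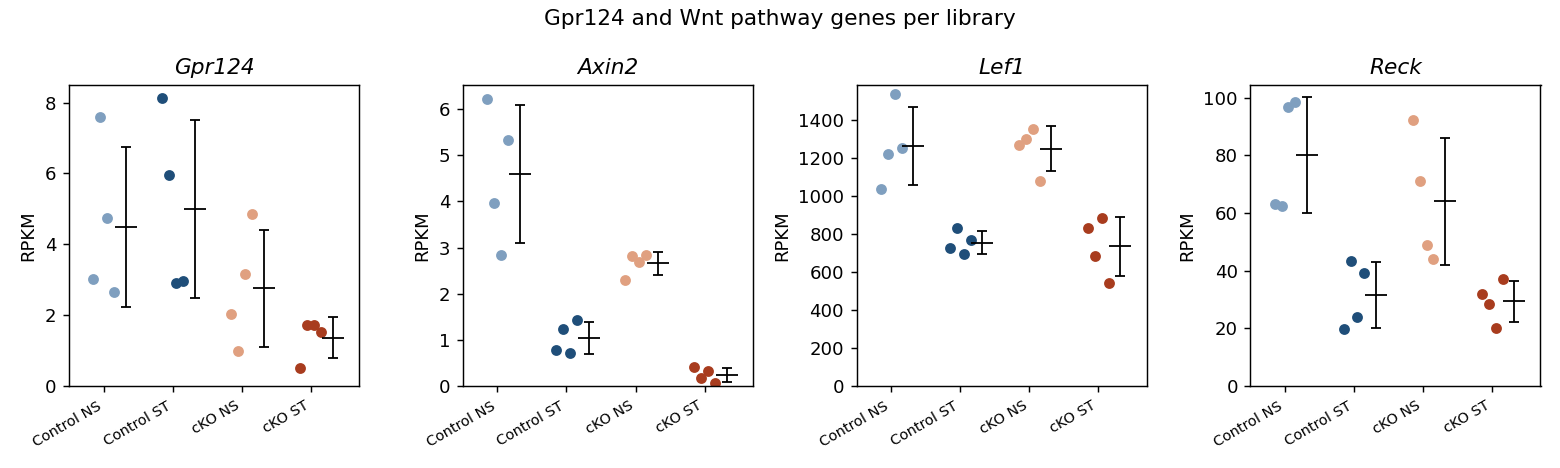
RPKM of Gpr124, Axin2, Lef1 and Reck in each library of the 4 stroke groups, with mean ± SD bars. Axin2 means were 4.59 in Control_NS, 1.04 in Control_ST, 2.66 in cKO_NS and 0.249 in cKO_ST.

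In controls 1308 of 9838 tested genes passed (832 rose, 476 fell), 817 and 512 with median-of-ratios scaling, 764 and 611 with quantile normalization. Of 29 transport genes 19 fell and 0 rose, 23 adjusted over the list alone (list adjusted p = 6.17e-16; adjusted p = 0.0543 with an estimated correlation). Of 23 inflammation genes 13 rose (14 adjusted over the list alone; adjusted p = 1.09e-07), and of 11 protease genes 6 rose and 1, Timp3, named after its value was seen, fell (-0.80; the same counts adjusted over the list alone; adjusted p = 2.86e-05). Of 15 basement-membrane genes 6 rose (7 adjusted over the list alone; adjusted p = 5.47e-05; adjusted p = 0.0840 with an estimated correlation). Of 14 Wnt-target genes 8 fell and 3 rose, the same adjusted over the list alone (direction down, adjusted p = 0.00731; adjusted p = 0.0919 with an estimated correlation). Reck and Lrp6 (-0.67 ± 0.21) fell among 15 Wnt-pathway components (adjusted p = 0.0194; adjusted p = 0.0977 with an estimated correlation). That call ended without Control_NS 3 (0.0564) or Control_ST 4 (0.0611). Of 11 leukocyte-adhesion genes 6 rose (6 and 1 lower adjusted over the list alone; adjusted p = 0.00454; adjusted p = 0.199 with an estimated correlation). Of 10 venous genes, among them Icam1, Ackr1 and Lcn2 of other lists, 5 rose (adjusted p = 9.84e-04; adjusted p = 0.0977 with an estimated correlation).

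Among 23 immediate-early genes Klf6 (0.68 ± 0.17) and Atf3 (1.84 ± 0.55) rose in controls (adjusted p = 0.0381; adjusted p = 0.577 with an estimated correlation; 0.183 with the GC trend removed). The astrocyte list of 3 genes passed (adjusted p = 0.0179; adjusted p = 0.0840 with an estimated correlation). Of its members Gja1, which endothelial cells also express, rose over all genes, and 2 rose adjusted over the list alone. Omission of 1 library ended the immediate-early call (0.0795 without Control_NS 1, 0.326 without Control_NS 4, 0.223 without Control_ST 3) and the astrocyte call (0.112 to 0.229 without Control_NS 4 or any 1 Control_ST library).

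The effect of stroke in Gpr124 knockouts, cKO_ST against cKO_NS, asks the same question where Gpr124 was targeted, and shares no library with the comparison in controls. Adamts4 rose by 4.70 ± 0.44, from 4.13 ± 2.91 to 119 ± 33.0 RPKM (n = 4 each, adjusted p = 3.31e-06), Adamts9 by 3.26 ± 0.25 and Adamts1 by 2.36 ± 0.25. Emp1 rose from 137 ± 11.7 to 2206 ± 377 (3.99 ± 0.36). Apln rose by 4.03 ± 0.40, AA467197 by 3.64 ± 0.44, the flippase Atp8b1 by 3.33 ± 0.49 and Inhbb by 3.29 ± 0.42. Sele rose by 3.34 ± 0.40 (0.157 ± 0.120 to 10.9 ± 3.08), Selp by 3.02 ± 0.36 (0.139 ± 0.179 to 8.81 ± 4.04), Icam1 by 1.97 ± 0.30 and Ackr1 by 2.42 ± 0.45. Il6 rose by 2.80 ± 0.39, the leukocyte growth factor Csf3 by 2.29 ± 0.42, Ptgs2 by 2.31 ± 0.34, the NF-kB inhibitor Tnfaip3 by 2.16 ± 0.38 and Lcn2 by 1.88 ± 0.44, with 266 in cKO_NS 3 and 944 in cKO_ST 3. Col4a1 rose by 1.35 ± 0.20, Col4a2 by 1.20 ± 0.20, Nid1 by 1.86 ± 0.28, Sparc by 1.26 ± 0.18, Gja1 by 1.68 ± 0.14 and Hmox1 by 3.11 ± 0.49. Mmp3 was 0.0766 ± 0.0825 and Mmp9 0.00529 ± 0.0106 in cKO_ST, below the filter.

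Transport genes fell in knockouts. Slco1c1, a thyroid-hormone carrier (GRCm38 chromosome 6, 141524368 to 141570177, plus strand), fell from 267 ± 22.3 to 48.8 ± 16.1 (-2.48 ± 0.25, adjusted p = 5.24e-06). Atp10a (-2.34 ± 0.23), the anion carrier Slc22a8 (-2.60 ± 0.35, 30.9 ± 8.48 to 4.20 ± 1.27), Lrp8 (-1.93 ± 0.22) and Abcc4 (-1.88 ± 0.22) fell. Abcb1a fell from 180 ± 40.0 to 53.9 ± 16.5 (-1.74 ± 0.22), with 78.4 in cKO_ST 3, and Mfsd2a by 1.39 ± 0.30. Slc2a1 fell from 6035 ± 1907 to 2726 ± 932 (-1.13 ± 0.24, adjusted p = 0.00410), with 4118 in cKO_ST 3. Bsg, a partner of lactate carriers, fell from 1203 ± 435 to 198 ± 60.8 (-2.58 ± 0.35). Ocln fell by 1.25 ± 0.18, Tjp1 by 0.97 ± 0.13, Jam2 by 0.77 ± 0.17 and the tricellular-junction gene Lsr by 0.74 ± 0.24. Cldn5 was 102 ± 24.0 against 162 ± 12.9 (-0.69 ± 0.23, adjusted p = 0.0510), and fell with the samples paired by number (adjusted p = 0.0245). The largest falls were in Sult1a1 (-3.37 ± 0.45, 219 ± 34.7 to 28.4 ± 29.4), Cytl1 (-3.11 ± 0.68), Rasgrp2 (-2.93 ± 0.35), Itih5 (-2.78 ± 0.30), Tecrl (-2.74 ± 0.55), Pik3ip1 (-2.61 ± 0.40) and Tcf15 (-2.59 ± 0.43). Cytl1 was 87.3 RPKM in cKO_NS 4 and 5.55 to 9.28 in the other cKO_NS libraries, so the size of its fall rests in part on cKO_NS 4.

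Axin2 fell in knockouts from 2.66 ± 0.246 to 0.249 ± 0.151 (-1.56 ± 0.26, adjusted p = 5.54e-04). Lef1 (-0.78 ± 0.16), Sox17 (-1.30 ± 0.21) and Notum, a Wnt-inactivating enzyme (-2.11 ± 0.34), fell as well. Reck fell by 1.07 ± 0.28 (64.0 ± 22.1 to 29.4 ± 7.08). Myc rose by 2.79 ± 0.30. Gpr124 was 1.37 ± 0.585 against 2.76 ± 1.65 (-0.60 ± 0.39, adjusted p = 0.328) and Plvap, a marker of fenestrated vessels, was 6.51 ± 6.00 against 1.47 ± 1.11 (1.36 ± 0.60, adjusted p = 0.139). The endothelial genes Ramp2 (-1.10 ± 0.25) and Tek (-0.80 ± 0.16) fell, and Emcn (0.80 ± 0.15) and Cdh5 (0.75 ± 0.16) rose.

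In knockouts 1491 of 9838 genes passed, and 634 rose and 857 fell. The median log2 fold change of all genes was -0.13, which moved to -0.01 with median-of-ratios scaling, where 868 rose and 599 fell (744 and 663 with quantile normalization, 832 and 660 with the GC trend removed). Of 29 transport genes 24 fell (25 adjusted over the list alone; list adjusted p = 1.20e-18). Of 23 inflammation genes 9 rose and Cxcl12, named after its value was seen, fell by 0.81 (12 and 1 adjusted over the list alone; adjusted p = 2.38e-07), and of 11 protease genes 6 rose and 1 fell (adjusted p = 1.43e-06). Of 11 leukocyte-adhesion genes 6 rose (adjusted p = 8.51e-04; adjusted p = 0.199 with an estimated correlation), and of 10 venous genes 5 rose (adjusted p = 0.00683; adjusted p = 0.199 with an estimated correlation). Of 14 Wnt-target genes 8 fell and 3 rose (direction down, adjusted p = 0.0238; adjusted p = 0.199 with an estimated correlation). Of 13 tight-junction genes 4 fell (5 adjusted over the list alone; adjusted p = 0.0362; adjusted p = 0.199 with an estimated correlation; 0.0621 with median-of-ratios scaling). Omission of 1 library ended the Wnt-target call (0.0597 without cKO_ST 4) and the tight-junction call (0.0509 to 0.0714 without cKO_NS 1, cKO_NS 4, cKO_ST 1 or cKO_ST 2).

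Of 15 basement-membrane genes in knockouts 6 rose and 3 fell (7 and 4 adjusted over the list alone; direction up, adjusted p = 0.0158; adjusted p = 0.226 with an estimated correlation). Klf6 (0.85 ± 0.17), Dusp1 (0.77 ± 0.24) and Hsp90aa1 (0.87 ± 0.29) rose among immediate-early genes (adjusted p = 0.0365; adjusted p = 0.723 with an estimated correlation). The 7 red-cell and platelet genes were lower as a list (adjusted p = 0.0212; adjusted p = 0.611 with an estimated correlation), 0 of them passed over all genes and 6 adjusted over the list alone. The globin Hbb-b1 was 1772 ± 2095 against 4646 ± 3940 (-1.79 ± 0.64, adjusted p = 0.0679; 3.37e-04 with pairing by number). Omission of 1 library ended the immediate-early call (0.0556 to 0.303 without cKO_NS 1, 2 or 3 or cKO_ST 1 or 4) and the red-cell call (0.0670 to 0.113 without cKO_NS 3 or cKO_ST 1 or 2). Across both genotypes 446 genes rose in both (53.6 if calls were independent), 330 fell in both (41.5 if independent) and 0 moved in opposite directions. The calls are not independent, because both comparisons come from 1 fit with a shared estimate of the spread of each gene.

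**Figure D2:**
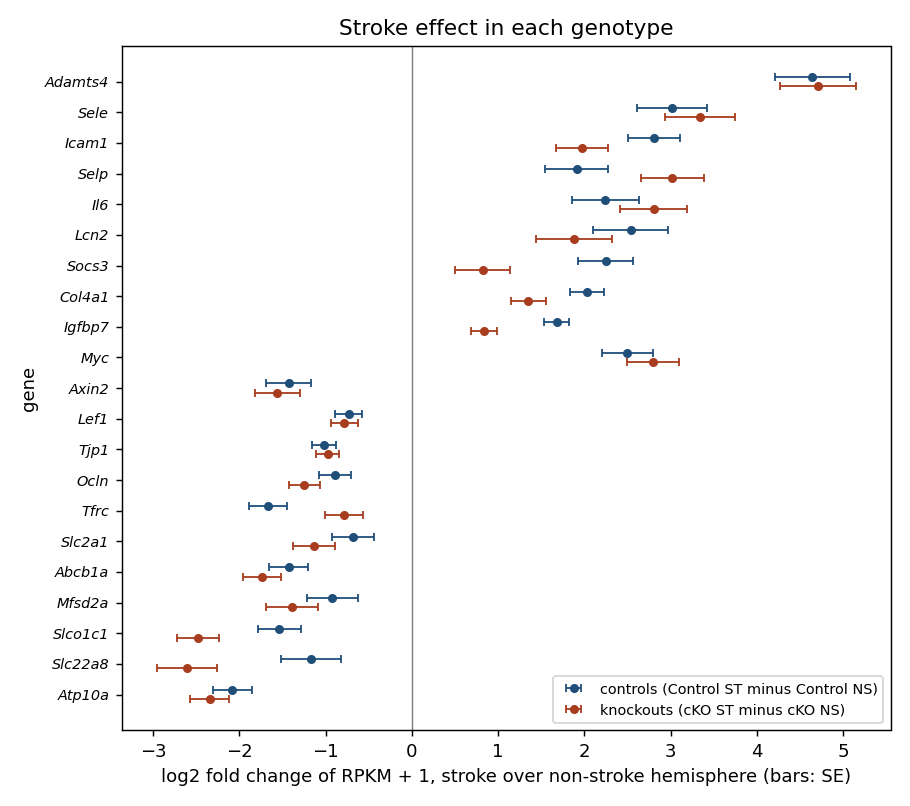
Log2 fold change ± SE of stroke over non-stroke hemisphere for 21 genes, controls in blue and knockouts in red. Adamts4 had 4.64 in controls and 4.70 in knockouts, and Atp10a had -2.08 and -2.34.

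The effect of genotype in the non-stroke hemisphere, cKO_NS against Control_NS, asks what loss of Gpr124 changes in adult brain endothelial cells away from the stroke. Igfbp7, a matrix protein of brain capillaries (GRCm38 chromosome 5, 77349240 to 77408041, minus strand), rose from 405 ± 31.6 to 888 ± 160 RPKM (1.12 ± 0.15, n = 4 each, adjusted p = 0.00466). The basement-membrane collagens Col4a2 (1.31 ± 0.20, 16.6 ± 3.41 to 43.0 ± 10.8) and Col4a1 (0.96 ± 0.20, adjusted p = 0.0460) rose, as did the guidance receptor Robo4 (1.17 ± 0.23, 71.4 ± 18.4 to 159 ± 23.7) and the nitric-oxide synthase Nos3 (1.40 ± 0.29, 10.4 ± 3.67 to 28.4 ± 6.93). Tfrc fell from 1002 ± 192 to 372 ± 80.2 (-1.44 ± 0.22, adjusted p = 0.0143). The lactate carrier Slc16a1 (GRCm38 chromosome 3, 104638668 to 104658462, plus strand) fell from 1854 ± 384 to 850 ± 205 (-1.13 ± 0.21, adjusted p = 0.0213).

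The kinase genes Map3k6 (1.85 ± 0.33, 50.3 ± 18.5 to 182 ± 58.7) and Mapk12 (1.80 ± 0.30) rose with Actr1b (1.87 ± 0.35), Sap30l (1.86 ± 0.39) and Uxt (1.78 ± 0.29). So did the mitochondrial ribosomal gene Mrpl23 (1.64 ± 0.29), the antioxidant gene Srxn1 (1.52 ± 0.28), Sorbs3 (1.38 ± 0.27) and Ctla2a (1.37 ± 0.23, 352 ± 53.8 to 929 ± 262). Hbb-y fell by 1.73 ± 0.30 on the log2 scale, Cetn2 by 1.11 ± 0.23, the transcription factor Sp1 by 1.00 ± 0.20 and Echdc1 by 0.86 ± 0.16. Rnf146, a ligase that marks axin for breakdown, fell by 0.81 ± 0.16 and Arhgap29 by 0.55 ± 0.11. Ctnnb1 was 1689 ± 214 against 2269 ± 158 (-0.43 ± 0.11, adjusted p = 0.0926). Axin2 was 2.66 ± 0.246 against 4.59 ± 1.49 (-0.57 ± 0.26, adjusted p = 0.329) and Lef1 1250 ± 120 against 1262 ± 205 (-0.01 ± 0.16). Reck was 64.0 ± 22.1 against 80.3 ± 20.1 (-0.35 ± 0.28), and Foxq1 162 ± 30.7 against 216 ± 37.9 (-0.42 ± 0.17). Barrier genes gave Cldn5 162 ± 12.9 against 112 ± 16.0 (0.53 ± 0.23) and Slc2a1 6035 ± 1907 against 4075 ± 82.9 (0.50 ± 0.24). Abcb1a was 180 ± 40.0 against 195 ± 20.1 (-0.14 ± 0.22) and Mfsd2a 41.2 ± 3.24 against 33.5 ± 8.57 (0.32 ± 0.30). Icam1 was 9.71 ± 4.07 against 3.25 ± 1.43 (1.32 ± 0.30, adjusted p = 0.0611) and Lcn2 126 ± 93.6 against 30.7 ± 5.13 (1.78 ± 0.44, adjusted p = 0.0772), with 266 in cKO_NS 3.

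In this comparison 31 of 9838 genes passed, and 22 rose and 9 fell. The median of all genes, 0.11, moved to -0.01 with median-of-ratios scaling, where 14 rose and 15 fell (18 and 14 with quantile normalization, 3 and 6 with the GC trend removed). Of 14 Wnt-target genes 11 were lower and 0 passed (list adjusted p = 0.00464; adjusted p = 0.206 with an estimated correlation). Of 15 Wnt components 10 were lower, 0 passed over all genes and 1, Ctnnb1, passed adjusted over the list alone (adjusted p = 0.0262; adjusted p = 0.206 with an estimated correlation). Of 22 hypoxia and glycolysis genes 20 were higher and 0 passed (adjusted p = 0.00464; adjusted p = 0.206 with an estimated correlation). Of 18 endothelial genes 15 were higher, and 1, Robo4, rose (7 adjusted over the list alone; adjusted p = 0.00464; adjusted p = 0.206 with an estimated correlation). Of 15 basement-membrane genes 11 were higher and 3 rose (4 adjusted over the list alone; adjusted p = 0.0165; adjusted p = 0.355 with an estimated correlation; 0.424 with the GC trend removed). Of 29 transport genes 14 were higher and 15 lower, and 2 fell (direction down, adjusted p = 0.0165; adjusted p = 0.558 with an estimated correlation). Of lists for other cells, the 3 blood-leukocyte genes were all higher (mean 2.05, adjusted p = 0.0642), 3 of 4 mural genes were lower (mean -0.65, 0.0623) and 9 of 11 oligodendrocyte genes were lower (mean -0.60, 0.0677), and 0 of these lists passed. Over all genes limma called 0 of their genes (S100a8, S100a9 and Mal had unadjusted p under 0.05), and S100a8 (2.87 ± 0.91) passed adjusted over its list alone. Without cKO_NS 4 the adjusted p was 0.0914 for Wnt components, 0.0902 for basement membrane and 0.0780 for transport, and without Control_NS 3 it was 0.118 for Wnt components.

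The genotype count was 1 (Igfbp7) without Control_NS 4, 9 without cKO_NS 3, 11 without Control_NS 1, 17 without cKO_NS 1 and 9 with the GC trend removed, and a fit to these 2 groups alone kept Igfbp7 and Tfrc. Rn45s, a ribosomal RNA precursor examined after its values were seen, moved with genotype: 85.6 ± 34.4 RPKM in cKO_NS against 251 ± 81.8 in Control_NS, and 73.7 ± 34.6 in cKO_ST against 197 ± 19.3 in Control_ST, with 134 as the highest knockout and 137 as the lowest control.

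The effect of genotype in the stroke hemisphere, cKO_ST against Control_ST, asks what Gpr124 changes after stroke. Axin2 was 0.249 ± 0.151 against 1.04 ± 0.347 RPKM (-0.70 ± 0.26, n = 4 each, adjusted p = 0.994), and the endothelial transcription factor Foxq1 79.1 ± 10.6 against 131 ± 20.3 (-0.71 ± 0.17, adjusted p = 0.575). The lactate carrier Slc16a1 was 393 ± 73.4 against 675 ± 155 (-0.77 ± 0.21, adjusted p = 0.645) and Abcb1a 53.9 ± 16.5 against 73.3 ± 16.5 (-0.45 ± 0.22). Slc2a1 was 2726 ± 932 against 2581 ± 536 (0.05 ± 0.24), and Mfsd2a 15.4 ± 4.02 against 18.7 ± 10.6 (-0.15 ± 0.30). Cldn5 was 102 ± 24.0 against 119 ± 51.3 (-0.16 ± 0.23) and Tjp1 128 ± 13.8 against 147 ± 14.7 (-0.21 ± 0.13). Ctnnb1 was 1964 ± 73.8 against 2044 ± 106 (-0.06 ± 0.11), and Lef1 736 ± 155 against 755 ± 60.1 (-0.06 ± 0.16). Reck was 29.4 ± 7.08 against 31.6 ± 11.3 (-0.06 ± 0.28) and Apcdd1 1.02 ± 0.804 against 1.79 ± 1.21 (-0.46 ± 0.37).

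Inflammatory genes gave Lcn2 461 ± 324 against 204 ± 120 (1.13 ± 0.44, adjusted p = 0.994), and Selp 8.81 ± 4.04 against 4.64 ± 2.86 (0.82 ± 0.36). Icam1 was 39.1 ± 2.23 against 29.3 ± 12.7 (0.49 ± 0.30), Sele 10.9 ± 3.08 against 15.1 ± 14.0 (-0.12 ± 0.40) and Vcam1 38.2 ± 31.2 against 40.6 ± 18.0 (-0.26 ± 0.50). The vasodilator peptide Adm was 486 ± 105 against 301 ± 69.4 (0.69 ± 0.32), and Emp1 2206 ± 377 against 1659 ± 634 (0.46 ± 0.36). Adamts9 was 349 ± 49.6 against 287 ± 40.3 (0.28 ± 0.25), Col4a1 138 ± 26.5 against 113 ± 10.2 (0.28 ± 0.20) and Igfbp7 1577 ± 206 against 1301 ± 176 (0.28 ± 0.15). Genes picked after their values were seen were Slco1c1 (-1.29 ± 0.25), Slc22a8 (-1.27 ± 0.35), Slc39a10 (-0.89 ± 0.20; GRCm38 chromosome 1, 46807544 to 46892852, minus strand), Itih5 (-1.59) and Itm2a (-1.39), none of which passed.

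In the stroke hemisphere limma called 0 of 9838 genes (lowest adjusted p = 0.288), with 476 at unadjusted p under 0.05, 166 higher and 310 lower. The list of 29 transport genes passed with direction down (adjusted p = 2.09e-13; adjusted p = 0.136 with an estimated correlation): 26 were lower, 0 passed over all genes and 11 did adjusted over the list alone. Of 14 Wnt-target genes 12 were lower (adjusted p = 8.35e-04; adjusted p = 0.131 with an estimated correlation), 0 passed over all genes and 1, Foxq1, passed adjusted over the list alone. Of 23 inflammation genes 15 were higher (adjusted p = 0.0136; adjusted p = 0.467 with an estimated correlation), and 0 passed by either adjustment. Mean log2(RPKM + 1) of the transport list per library was 4.93 ± 0.18 in cKO_ST against 5.46 ± 0.37 in Control_ST, 3.54 ± 0.12 against 3.87 ± 0.15 for Wnt targets and 4.53 ± 0.12 against 4.20 ± 0.26 for inflammation (SD, n = 4 each). Library weights gave 5 genes and omission of Control_ST 3 gave 8 or of cKO_ST 3 gave 3, all lower in knockouts. The inflammation list lost its call without Control_ST 1 (adjusted p = 0.264), Control_ST 2 (0.0632) or cKO_ST 3 (0.0700), and Rn45s parted the genotypes here as in the non-stroke hemisphere.

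**Figure D3:**
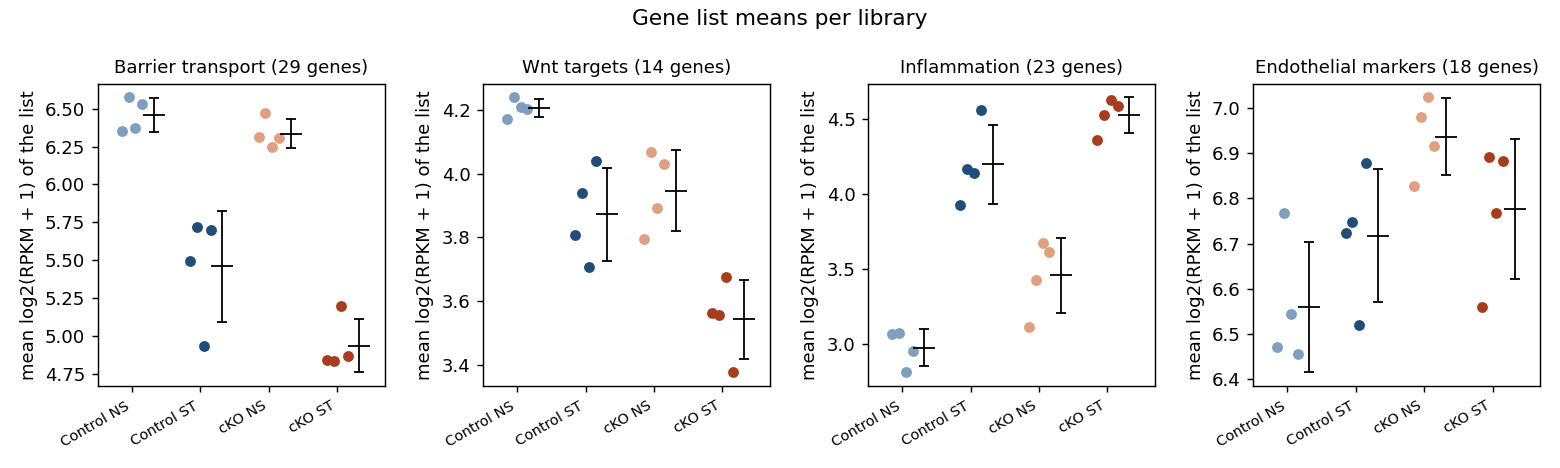
Mean log2(RPKM + 1) of the transport (29 genes), Wnt-target (14), inflammation (23) and endothelial (18) lists in each library of the 4 stroke groups, with mean ± SD bars. The transport list had means of 6.46 in Control_NS, 5.46 in Control_ST, 6.33 in cKO_NS and 4.93 in cKO_ST.

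The interaction, the stroke effect in knockouts minus that in controls, asks whether Gpr124 changes the response to stroke. Igfbp7 had -0.84 ± 0.21 (n = 4 per group, adjusted p = 0.681), Col4a1 -0.68 ± 0.28, the endothelial surface genes Ly6a -0.68 ± 0.22 and Ly6c1 -0.69 ± 0.24, which share similar sequence, and Cldn5 -0.69 ± 0.32 (adjusted p = 0.702). Selp had 1.10 ± 0.52, Icam1 -0.83 ± 0.43, Sele 0.33 ± 0.57, Vcam1 -0.05 ± 0.71 and Lcn2 -0.65 ± 0.62. Wnt-pathway genes had -0.71 ± 0.55 for Gpr124, -0.13 ± 0.37 for Axin2, -0.05 ± 0.22 for Lef1, 0.29 ± 0.40 for Reck, 0.37 ± 0.16 for Ctnnb1 and -0.29 ± 0.25 for Foxq1. Transport genes had -0.45 ± 0.34 for Slc2a1, 0.35 ± 0.29 for Slc16a1, -0.31 ± 0.32 for Abcb1a and -0.47 ± 0.42 for Mfsd2a, and junction genes 0.04 ± 0.19 for Tjp1 and -0.36 ± 0.26 for Ocln. The glycolysis gene Aldoa had -0.74 ± 0.34, the pericyte gene Rgs5 1.78 ± 0.85, the neuronal gene Snap25 -1.59 ± 0.73 and the neutrophil gene S100a8 -3.16 ± 1.29.

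For the interaction limma called 0 of 9838 genes (lowest adjusted p = 0.447), with 691 at unadjusted p under 0.05, 118 higher and 573 lower, and a median over all genes of -0.14. These counts are without rescaling. Median-of-ratios scaling moved the medians of stroke in knockouts and of genotype in the non-stroke hemisphere close to 0, so the excess of lower genes may depend on scaling. Of 15 basement-membrane genes 12 were lower and 0 passed over all genes (adjusted p = 0.0391; adjusted p = 0.496 with an estimated correlation), and adjusted over the list alone 2 did, Igfbp7 and Col4a2 (named after its value was seen). Of 22 hypoxia and glycolysis genes 20 were lower and 0 passed (adjusted p = 0.0422; adjusted p = 0.496 with an estimated correlation). Knockouts against controls, these 2 lists had means of 0.37 and 0.44 in the non-stroke and -0.07 and -0.03 in the stroke hemisphere. Their interaction thus lay mainly in the non-stroke hemisphere. With the GC trend removed the adjusted p was 0.383 for basement-membrane and 0.200 for hypoxia and glycolysis genes. Omission of 1 library ended the basement-membrane call for Control_NS 3, Control_ST 4, cKO_NS 2, cKO_NS 4 and cKO_ST 1 (0.0592 to 0.111). The hypoxia and glycolysis call ended for these and for Control_NS 4, Control_ST 1, cKO_NS 3 and cKO_ST 4 (0.0507 to 0.120). In the self-test 11.4% of true 2-fold and 70.4% of true 4-fold differences were recovered, among genes above about 5 RPKM.

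The beta-catenin comparison, Bcat_exon3 (n = 3) against Bcat_control (n = 2), asks which genes stabilised beta-catenin changes in brain endothelial cells without stroke. Wnt feedback genes were higher as means: Axin2 48.4 ± 5.42 against 27.3 ± 1.45 RPKM (0.80 ± 0.26, adjusted p = 0.901) and Apcdd1, an inhibitor at the cell surface (GRCm38 chromosome 18, 62922231 to 62961179, plus strand), 122 ± 34.1 against 56.4 ± 4.02 (1.06 ± 0.27, adjusted p = 0.769). Lef1 was 83.9 ± 9.73 against 126 ± 36.6 (-0.56 ± 0.26) and Reck 75.5 ± 44.9 against 61.2 ± 10.3 (0.16 ± 0.42). Vcam1 was 58.3 ± 21.1 against 14.5 ± 10.4 (2.05 ± 0.48, adjusted p = 0.672), and Icam1 13.7 ± 7.60 against 6.12 ± 0.313 (0.88 ± 0.55). The plasminogen activator Plat was 253 ± 14.3 against 118 ± 14.5 (1.09 ± 0.21, adjusted p = 0.494) and fibronectin, Fn1, 520 ± 51.9 against 283 ± 36.3 (0.88 ± 0.22, adjusted p = 0.708). The vein genes Vwf (0.80 ± 0.62) and Il1r1 (0.91 ± 0.42), the muscle gene Acta2 (1.96 ± 0.81) and the globin Hbb-b1 (9813 ± 3654 against 6158 ± 230) were higher as means.

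**Figure D4:**
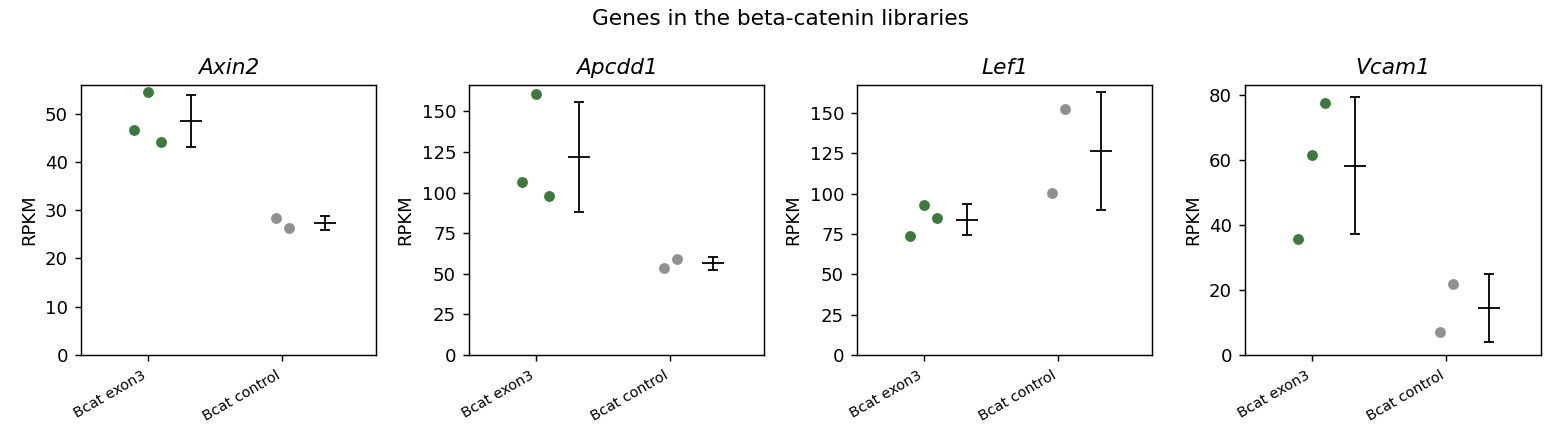
RPKM of Axin2, Apcdd1, Lef1 and Vcam1 in each Bcat_exon3 and Bcat_control library, with mean ± SD bars. Axin2 means were 48.4 in Bcat_exon3 and 27.3 in Bcat_control.

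Barrier genes had Cldn5 183 ± 25.5 against 163 ± 59.6 (0.21 ± 0.28), Slc2a1 1763 ± 504 against 1829 ± 619 (-0.05 ± 0.32), and Abcb1a 455 ± 14.9 against 413 ± 9.80 (0.14 ± 0.20). Mfsd2a was 150 ± 32.5 against 134 ± 9.40 (0.15 ± 0.25), Slco1a4 1473 ± 321 against 1298 ± 140 (0.16 ± 0.26), Tjp1 383 ± 31.4 against 354 ± 32.3 (0.11 ± 0.21) and Plvap 1.11 ± 1.23 against 2.70 ± 3.16 (-0.66 ± 0.86). Col4a1 was 38.5 ± 6.24 against 38.1 ± 1.74 (0.00 ± 0.27), and Pdgfb 41.4 ± 8.03 against 54.1 ± 9.66 (-0.39 ± 0.28). Pecam1 was 227 ± 60.8 against 267 ± 30.7 (-0.26 ± 0.26), B2m 1434 ± 597 against 1843 ± 52.3 (-0.47 ± 0.37) and Cxcl12 252 ± 59.6 against 370 ± 33.9 (-0.58 ± 0.26). Genes picked after their values were seen were the Wnt inhibitors Nkd1 (2.33 ± 0.50; GRCm38 chromosome 8, 88521354 to 88594884, plus strand), Nkd2 (2.02 ± 0.56) and Dkk2 (2.55 ± 0.64), and the vein genes Ackr1 (3.17 ± 0.63) and Lcn2 (4.36 ± 0.96). So were Alas2 of red cells (1.25 ± 0.30), Jam2 (-1.12 ± 0.22), Ifit3 (-1.25 ± 0.31) and the arterial genes Alpl (-1.39 ± 0.33) and Gkn3 (-2.60 ± 0.64), and none of these passed. Mmp3 and Mmp9 were 0 in all 5 libraries.

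Here limma called 0 of 11252 genes (lowest adjusted p = 0.216), with 590 at unadjusted p under 0.05, 250 higher and 340 lower, and 0 list members passed over all genes. Of 16 Wnt-target genes 11 were higher (adjusted p = 2.26e-05; adjusted p = 0.311 with an estimated correlation), 5 adjusted over the list alone: Nkd1, Dkk2, Apcdd1, Nkd2 and Axin2. Of 10 venous genes 9 were higher (adjusted p = 2.43e-06; adjusted p = 0.311 with an estimated correlation), 3 adjusted over the list alone: Ackr1, Lcn2 and Vcam1. All 7 red-cell and platelet genes were higher (adjusted p = 5.24e-07; adjusted p = 0.377 with an estimated correlation), 3 adjusted over the list alone, with globin names of near-identical sequence counted apart. Of 29 interferon genes 26 were lower (adjusted p = 1.22e-05; adjusted p = 0.377 with an estimated correlation), 0 adjusted over the list alone. Of 18 inflammation genes 13 were higher (adjusted p = 0.00283; adjusted p = 0.311 with an estimated correlation), 1, Lcn2, adjusted over the list alone. Of 9 leukocyte-adhesion genes 5 were higher (adjusted p = 0.00736; adjusted p = 0.311 with an estimated correlation), 2 adjusted over the list alone. Of 10 protease genes 8 were higher (adjusted p = 0.0140; adjusted p = 0.311 with an estimated correlation), and Plat passed adjusted over the list alone. The protease call ended without Bcat_exon3 1 (0.0555) or Bcat_control 2 (0.124).

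Of 8 mural genes, which mark pericytes and smooth muscle, 7 were higher (adjusted p = 0.0143; adjusted p = 0.557 with an estimated correlation), 0 adjusted over the list alone. Of 17 basement-membrane genes 10 were higher (adjusted p = 0.0392; adjusted p = 0.348 with an estimated correlation), and Fn1 passed adjusted over the list alone. Omission of 1 library ended the mural call (0.111 to 0.197 without Bcat_exon3 2 or 3 or either control) and the basement-membrane call (0.0801 to 0.169 without Bcat_exon3 1 or 2 or either control), and a lone control is then assumed to vary like the other group. In the self-test of this design 0% of true 2-fold and 5.20% of true 4-fold differences were recovered, among genes above about 5 RPKM. Rn45s was 6588 ± 2099 in Bcat_exon3 against 9505 ± 355 in Bcat_control.

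Genes of the beta-catenin comparison were then followed in the stroke experiment, which asks whether Gpr124 acts on the same genes. Because 0 genes passed there, the 50 genes of lowest p in each direction were used, of which 43 and 41 were tested. The 43 genes higher in Bcat_exon3 had direction down in knockouts in both hemispheres, with adjusted p = 0.0859 in the non-stroke and 0.0734 in the stroke hemisphere. The 41 genes lower in Bcat_exon3 gave adjusted p = 0.464 and 0.475, and 0 of 10 set tests passed.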

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

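The 31 genes and 5 library measures examined for single deviating libraries were picked after their values were seen, and the splits of the interaction by unadjusted p were chosen because its adjusted count was 0. Of 144 groups of 4 libraries, 11 held a library far from the other 3 by Dixon's test, where chance gives about 1 in 20, or 7.2.

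Gpr124 was 0.500 RPKM in cKO_ST 1 and 1.52 to 1.72 in the other 3 libraries of that group. In cKO_ST 3 Slc2a1 was 4118 (others 2149 to 2342), Abcb1a 78.4 (42.6 to 48.7) and Lcn2 944 (269 to 344). Lcn2 was also far higher in cKO_NS 3, at 266 against 73.2 to 83.9, and Ocln in cKO_NS 2, at 275 against 221 to 224. In Control_ST 4 Cldn5 was 195 (84.1 to 99.6) and Sele 35.8 (4.99 to 9.92), and in Control_ST 3 Emp1 was 2602 (1231 to 1433). In Control_NS 4 Il6 was 0.0630 and 0 in the others, and in Control_NS 1 Actb was 8658 against 7163 to 7375.

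The sum of 4 Y-linked genes, which no comparison used, was 189 RPKM in cKO_NS 4, a library labelled female, against 0.228 to 1.77 in the female libraries. In cKO_ST 4, labelled male, the sum was 249. Libraries were kept as labelled. Over the 832 genes that rose with stroke in controls, a measure chosen after the mismatch was seen, the mean log2(RPKM + 1) was 4.47 in cKO_NS 4 (4.31 to 4.46 in the other cKO_NS) and 5.20 in cKO_ST 3, which reads female under a male label (5.33 to 5.54 in the other cKO_ST). These values argue against an exchange of the 2 libraries, and other exchanges of animals within knockouts stay open. By RNA, both knockout libraries numbered 3 read female and both numbered 4 read male. Each of these numbers correlated best with its own, at 0.214 for number 3 (other pairs at most 0.0543) and 0.105 for number 4 (at most 0.0147).

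Basement-membrane genes (adjusted p = 0.0391, 12 of 15 lower) and hypoxia and glycolysis genes (adjusted p = 0.0422, 20 of 22 lower) passed the interaction test with a preset correlation. Their mean log2 fold changes in knockouts against controls were 0.37 and 0.44 in the non-stroke hemisphere. In the stroke hemisphere they were -0.07 and -0.03, so the difference lay mainly in the non-stroke hemisphere. The adjusted p was 0.496 for both with an estimated correlation, and 0.383 and 0.200 with the GC trend removed. Of 100 drawn splits, 63 passed as many lists as the real 2, with a highest other of 9, and 13 passed as many genes at unadjusted p under 0.05 as the real 691, with a highest other of 973, so chance could not be excluded for either.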

How the results depend on the processing

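Sex read from RNA, omission of libraries by RNA sex, the GC trend and omissions of single libraries for lists and sets were chosen only after results were seen. Genes called in neither of the fits compared were counted as unchanged even where their sign differed. For the sets of beta-catenin genes, sets of the 100 largest changes past the threshold gave no value because limma called 0 genes (590 at unadjusted p under 0.05).

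Under most alternatives the counts of genes past the threshold for stroke stayed within 1.5 times those reported, between 1096 and 1797 in controls and between 1078 and 1985 in knockouts. In knockouts more genes fell (857) than rose (634) as reported, and more rose than fell with median-of-ratios scaling (868 and 599), quantile normalization (744 and 663), the GC trend removed (832 and 660) and block and GC removal (877 and 680); the cause was not tested. A minimum 2-fold change left 852 of 1308 genes in controls and 961 of 1491 in knockouts, by construction of the threshold. With sex as labelled, 993 genes passed in knockouts, and the cause was not tested. Omission of single libraries gave 993 (without Control_NS 4 or Control_ST 3) to 1113 genes in controls, and 1044 (without cKO_ST 1) to 1513 in knockouts.

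In the non-stroke hemisphere genotype gave 31 genes as reported, 19 without a filter, 84 at 5 RPKM, 125 with library weights and 12 without a trend. It gave 60 with a block for the sample number, which ties samples of different genotype, and 2 in a fit to the compared groups alone (fewer libraries, Igfbp7 and Tfrc). Sex as labelled gave 18, sex from RNA 60, omission of libraries male by RNA 75, removal of the GC trend 9, and block and GC removal 11. Except for the fit to fewer libraries, the cause was not tested. Omission of single libraries gave 1 (without Control_NS 4) to 41 (without cKO_NS 4).

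Genotype after stroke gave 0 genes in limma (476 at unadjusted p under 0.05), 5 with library weights (Slco1c1, Slc39a10, Itih5, Tspan13 and Itm2a, named after their values were seen), and 0 to 8 on omission of single libraries, with 8 without Control_ST 3 and 3 without cKO_ST 3 (Itih5, Slco1c1 and Ccdc141, also named afterwards); the cause was not tested. The interaction (691 unadjusted) and beta-catenin comparisons (590 unadjusted) had 0 under every alternative run.

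Of 40 list calls 5 held with an estimated correlation. With fry 35 lists passed, in part others: it shared 9 calls for stroke in controls, 8 for stroke in knockouts, 4 for genotype in the non-stroke hemisphere, 1 for genotype after stroke, 0 for the interaction and 1 for the beta-catenin comparison. In genotype after stroke, the transport list had adjusted p of 0.136 with an estimated correlation and 0.0794 with fry, and Wnt targets 0.131 with an estimated correlation; the cause was not tested. Omission of single libraries gave 1.02e-18 to 1.20e-08 for transport and 1.94e-04 to 0.0168 for Wnt targets. Of 10 beta-catenin set tests 0 passed as reported, 1 without libraries labelled male, and 0 to 1 on omission of single libraries (1 without Control_NS 1, Control_ST 3 or cKO_ST 3); the cause was not tested.

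With a block for the sample number 45 lists passed, 1460 genes in controls and 1576 in knockouts. In controls the block rests on numbers of which 3 of 4 correlated best with their own, so pairing there stays open. In the genotype and beta-catenin comparisons it ties samples of different genotype, which the labels do not pair. Of same-numbered Control_NS and cKO_NS libraries only number 1 (0.0601) correlated best with its own, and none did between Control_ST and cKO_ST. The block moved oligodendrocyte (0.166 to 0.00908) and red-cell and platelet genes (0.0576 to 6.81e-05) past the threshold in controls, inflammation (0.0554 to 0.0401) and oligodendrocyte genes (0.0677 to 0.00343) in genotype in the non-stroke hemisphere, and transport (0.0632 to 0.0312) and red-cell and platelet genes (0.609 to 0.0197) in the interaction. In the beta-catenin comparison mural genes went from 0.0143 to 0.119. Named genes past the threshold kept their call in every alternative for 53 of 77 in controls, 63 of 81 in knockouts and 0 of 22 in genotype in the non-stroke hemisphere, and 0 reversed. Depth limits genes of low RPKM, whose fold changes depend on the pseudocount.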

Other observations

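The tests of dilution, of a swap, of a genotype-linked batch and of GC content for the transport list, of GC content and of a single library over all tested genes for genotype in the non-stroke hemisphere, and of blood in the beta-catenin comparison were chosen only after results were seen, as were the 2 lists singled out after stroke (inflammation passed too).

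After stroke the glycolysis gene Pgk1 rose by a log2 fold change of 1.74 ± 0.25 in controls and 1.24 ± 0.25 in knockouts (SE, n = 4 each), and the caveolar gene Sdpr fell by 1.74 ± 0.20 and 1.67 ± 0.20. The recycling gene Ehd4 rose by 1.01 ± 0.19 and 1.23 ± 0.19, the Notch ligand Jag1 fell by 0.88 ± 0.17 and 1.22 ± 0.17, the growth factor Tgfb2 fell by 1.49 ± 0.33 and 1.46 ± 0.33, and the phosphatase Ptprb fell by 0.72 ± 0.18 and 0.77 ± 0.18. The cytoskeletal linker Vcl rose by 0.56 ± 0.16 and 1.14 ± 0.16, the arterial phosphatase Alpl fell by 1.52 ± 0.41 and 2.11 ± 0.41, and the proteasome gene Psmb9 fell by 1.18 ± 0.38 and 2.12 ± 0.38. In controls Smad1 (0.79 ± 0.17), Smad6 (1.07 ± 0.33), Id1 (0.64 ± 0.20) and Pcna (0.91 ± 0.24) rose and the microglial P2ry12 fell (-1.56 ± 0.50). In knockouts Prkcdbp rose (0.98 ± 0.29), and Tgfbr2 (-0.75 ± 0.18), Gbp2 (-0.88 ± 0.26), Ndrg1 (-1.91 ± 0.43), Ctss (-2.06 ± 0.53) and Snap25 (-1.90 ± 0.51) fell. Whether these differ between genotypes was tested by the interaction, in which limma called 0 genes (691 at unadjusted p under 0.05).

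Markers of other cells were seen at varying levels despite the sort. Cldn11 was 507 ± 371 RPKM in Control_NS and 388 ± 365 in Control_ST, and Rgs5 of pericytes 49.0 ± 8.04 and 19.2 ± 17.7 (SD, n = 4 each), neither past the threshold. S100a9 of neutrophils was 0.403 ± 0.805 and 13.2 ± 15.8 (2.24 ± 0.89, adjusted p = 0.109), and choroid-plexus Ttr was 542 ± 538 in cKO_NS and 279 ± 477 in cKO_ST (-2.53 ± 1.23, adjusted p = 0.182; 0.0335 with pairing by number), with Enpp2 at -1.28 ± 0.48 (0.0793; 0.0174 with pairing).

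Lists that passed in no comparison gave, for stroke in controls and in knockouts, adjusted p of 0.275 and 0.104 for adherens junctions, 0.324 and 0.104 for vesicles and permeability, 0.941 and 0.918 for proliferation, 0.303 (controls) for angiogenesis, 0.275 and 0.953 for TGF-beta and BMP signalling, 0.242 and 0.472 for arterial genes, 0.389 and 0.0806 for neurons, 0.166 and 0.769 for oligodendrocytes, 0.389 and 0.715 for microglia and macrophages, 0.141 and 0.834 for blood leukocytes and 0.167 and 0.231 for the choroid plexus. The fibroblast list was tested in the beta-catenin comparison alone (0.794), where transport genes had 0.330.

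For the count of genes in genotype in the non-stroke hemisphere (real 31, highest other 3), 1 of 35 splits, the real one, gave as many. This argues against chance and does not exclude it. The share is the smallest that 35 splits allow and was not adjusted for the other split tests. For stroke in controls 1 of 35 did too (1308 and 1), which argues against chance only if same-numbered control libraries are not pairs. That stays open in controls, and with pairs the splits that part every pair number 8 there as well. For stroke in knockouts 1 of 35 gave as many too (1491 and 124), but the 8 splits that part every pair are too few for a share under 0.05 (1491 genes and 10 lists, highest others 0 and 9). The other 27 splits keep some pairs together. For lists, 3 of 35 splits gave as many for stroke in controls (10 and 10) and 2 for genotype in the non-stroke hemisphere (6 and 6), so chance could not be excluded for either. After stroke, 7 of 35 splits gave as many genes between genotypes at unadjusted p under 0.05 (476 and 760), a measure chosen because the adjusted count was 0, and 23 of 35 as many lists (3 and 6), so chance could not be excluded for either count.

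After stroke, transport genes had a mean log2 fold change of -0.53 in knockouts against controls and Wnt targets of -0.33, and 2 of 35 splits gave a transport mean as far from 0 (highest other -0.66) and 1 of 35 a Wnt mean (highest other -0.31), but both lists were picked because they had passed, so these splits do not exclude chance. GC content as the cause needs a transport mean of -0.26 or nearer 0 once its trend is removed, and the mean stayed at -0.50, which argues against it. Dilution by other cells would have lowered endothelial markers by a like amount. Their mean was 0.058, with a 95% interval over the genes, not the libraries, of -0.03 to 0.15. Per library the endothelial list had 6.78 ± 0.15 in cKO_ST against 6.72 ± 0.15 in Control_ST (SD, n = 4 each). These values argue against dilution. A library batch that follows genotype cannot be told apart from Gpr124, since Rn45s was at most 134 RPKM in knockouts and at least 137 in controls; within groups the list mean had a slope on log2 Rn45s of 0.043 for transport and 0.021 for Wnt targets, where 0.33 and 0.21 would be needed and the intervals end at 0.29 and 0.15. A loss of Wnt input through Gpr124 may lower these genes, which remains a hypothesis found on the same data. The transport, Wnt-target and inflammation lists differed between genotypes in the direction in which stroke moved them in controls. The protease and basement-membrane lists, which had direction up with stroke in controls, did not pass between genotypes (camera adjusted p = 0.405 and 0.997). Whether the extent of stroke differed between cKO_ST and Control_ST was not tested, so such a difference stays open too.

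The larger transport split exchanged Control_ST 3 and cKO_ST 3, and a swap of these libraries could have produced it. Rn45s argues against a swap of finished libraries: cKO_ST 3 had 76.4, with 176 to 217 in the other Control_ST libraries. Control_ST 3 had 185, with at most 113 in the other cKO_ST libraries. If Rn45s marks a library batch, it cannot show an exchange of cells before library preparation.

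In the non-stroke hemisphere, more genes were higher than lower in knockouts (22 and 9). With median-of-ratios scaling slightly more genes fell than rose, as given above, so this excess depends on the scaling. Under the reported scaling the values argue against a single library: of the 1405 genes at unadjusted p under 0.05, 74.7% were higher, and 71.0% or more without each library in turn (jackknife SE 4.67), with more rises than falls each time, although without Control_NS 4 only 1 gene passed. The median of the 22 genes stayed at 1.23 or above, which decides nothing because they were called with all libraries in. GC content may account for part of the excess: the genes that rose had a median GC content of 54.6%, at the 99.95 percentile of random sets, against 48.5% in all tested genes, and with the GC trend removed their median log2 fold change went from 1.29 (SE 0.24) to 1.05 (SE 0.23), against -1.11 (SE 0.21) to -1.07 (SE 0.20) for the genes that fell. With it removed 3 of 22 and 4 of 9 genes kept their call, 2 others passed (Slc7a1 and Tiam1, named after their values were seen), and the cause was not tested. A depth test put the median RPKM of the called genes, 55.9, at the 100 percentile, which decides nothing because abundant genes are easier to call at any depth, and an effect of Gpr124 on matrix and endothelial genes stays open too.

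In the beta-catenin comparison venous genes had a mean log2 fold change of 1.33, higher for 9 of 10 genes. The values argue against a single library, since the lowest mean without each library in turn was 1.05. Blood in the sorted cells, which the CD45 and CD31 gates would remove in part, cannot be told apart. The 3 blood-leukocyte genes had a mean of 0.46 with an interval, over the genes and not the libraries, of -1.66 to 2.58. The 7 red-cell and platelet genes, of cells that the CD31 gate would remove where they lack CD31, were all higher (mean 0.80, adjusted p = 5.24e-07 in camera with the preset correlation and 0.377 with an estimated correlation). A shift toward venous identity by beta-catenin may also account for it, and was not tested apart from these values.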
